A study of Homo sapiens with 18 samples.

How the data were processed

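Chromatin bound by estrogen receptor α (ERα) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 breast cancer cell lines, MCF7 and T47D, edited to carry wild-type (WT), Y537S or D538G ESR1. The series holds 18 samples: 12 immunoprecipitated libraries, 1 per line, genotype and treatment, and 6 input libraries, 1 per line and genotype. Peak lists of the 12 immunoprecipitated libraries were analysed, and the inputs were not analysed here. Per the labels' protocols, cells were kept for 3 days in 5% (MCF7) or 10% (T47D) charcoal-stripped serum and then given 1 nM estradiol (E2) or 1% ethanol for 45 min, and at least 10 ng of precipitated DNA per sample was sequenced as 50 bp single-end reads. DNA of individual clones was pooled before sequencing, per the series' design text, so each condition is 1 library.

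The authors aligned the reads and called the peaks before deposit. The tools named are Bowtie2 2.0, MACS 1.4, DiffBind and ChIPseeker, on build hg38, per the submitters' processing notes, which give no role or order. Peaks were listed per library. Whether the inputs served as the peak caller's control, and with which settings, is not given in the sources used here. Each deposited list gives a peak's chromosome, start and end and a score, which is the authors' own value per peak. Because scores depend on the reads in a library, they were used to rank, filter or describe peaks within a list, and set side by side across lists only in 1 check of depth.

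The lists record no read counts, so depth per library is unknown. The labels state only that over 16 M reads were allocated to each sample. A list's length depends on depth and on pull-down efficiency as well as on binding, and neither can be separated from genotype or treatment with 1 library per condition. Confidence intervals of shares (95%, exact Clopper-Pearson) and of ratios of peak numbers (95%, exact conditional binomial) cover counting error only. A share of 0 is given with the limit that 3 peaks of the total would set.

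All contig names in the lists occur in the hg38 reference, and 0 peaks ended beyond their chromosome's end. Coordinates are printed 1-based. Genes, transcription start sites (TSSs) and exons came from GENCODE 44, using 19962 protein-coding genes on chromosomes 1 to 22 and X. Peaks on all contigs were kept. Location was taken from the peak's centre, as promoter (within 1 kb of a TSS), exon, intron or intergenic, in this order. A gene was counted as having a peak when a peak reached within 50 kb of any of its TSSs, so that neighbouring genes can share a peak.

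Lists were compared by overlap of at least 1 bp. The number overlapping was set against 1000 random placements of the peaks, at their own widths, in sequenced bases of their own chromosomes, which gives a 1-sided permutation p of 0.001 at the smallest. The palindromic estrogen response element (ERE, GGTCANNNTGACC with at most 1 mismatch) and the single ERE arm (GGTCA), forkhead, GATA, AP-1, AP-2 and CTCF motifs were searched on both strands over the whole peak. Each motif's share was set against 100 random placements, whose smallest 1-sided permutation p is 0.0099. Classes of peaks within a list were compared by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment, over 70 tests for motifs and 10 for promoters. The WT E2 sites found in the vehicle lists of Y537S and D538G were compared by an exact McNemar test. The E2 contrast over the 6 pairs of lists was tested by an exact 2-sided sign-flip permutation test. Mutant and WT list lengths were compared on the log2 scale within blocks of line and treatment, by exact 2-sided permutation of the WT label among the 3 lists of each block. The sign-flip test, the block test and the check of depth have lists as their units. The other tests, the McNemar test included, describe these lists, since peaks and genes are not biological replicates.

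There were 11 gene lists, with 216 different genes: estrogen targets, luminal regulators, cell cycle, junctions and adhesion, matrix proteases, Wnt pathway, insulin-like growth factor and insulin, basal markers, epithelial-mesenchymal transition and migration, housekeeping and other tissues. The number of members with a peak was set against 10000 random lists of the same size matched on quintiles of gene length (1-sided permutation test). Values were Benjamini-Hochberg adjusted over all lists and libraries, and also adjusted over the list alone, with 0.05 as threshold.

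Genes and sites were named by a rule. It takes estrogen targets with a peak within 50 kb, then up to 8 members of each other list, first those with a mutant peak and no WT peak in a line and then those with peaks in most lists. It also takes the 5 peaks of highest score per list, the 5 mutant-only vehicle peaks of highest score per mutant list, and the 5 regions present in most of the 12 lists.

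The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Those alternatives were a score of at least 100, the 500 highest scores, chromosomes 1 to 22 and X, covered base pairs, overlap of 50% of the shorter peak or centres within 500 bp, moves of 10 to 100 kb in place of random placement, a perfect ERE, 200 bp around the peak centre, promoters of 3 kb, gene windows of 20 or 100 kb, random gene lists without matching, and leaving out each pair of lists. The block test of mutant and WT list lengths, counting ERE peaks only, leaving out peaks of the WT vehicle lists, and leaving out satellite peaks were added after the data were seen. A satellite peak has at least 10% of its bases in the repeated word GGAAT or its complement.

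The computations ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 20. They were tested on simulated data. For the MCF7 D538G vehicle peaks on the MCF7 WT E2 list, 300 of 300 planted overlaps were found, and 4% of 200 unrelated placements gave a permutation p under 0.05. The motif search found 200 of 200 planted EREs. Of 300 random gene lists of 30 genes, 2.67% gave a permutation p under 0.05.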

Results

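ERα binding was mapped by ChIP-seq in MCF7 and T47D, established breast cancer cell lines that grow in response to estrogen. The cells carried WT ESR1 or a Y537S or D538G substitution in the ligand-binding domain of the receptor, changes that are known from endocrine-resistant breast cancer. Each line and genotype was treated with vehicle or E2, giving 12 conditions with 1 library of pooled clones each. In MCF7, the vehicle lists held 125 (WT), 657 (Y537S) and 1016 (D538G) peaks, and the E2 lists held 12472, 1847 and 5403. In T47D, the vehicle lists held 615, 1096 and 1468 peaks and the E2 lists 1724, 3300 and 9552, in the same order of genotypes. Median peak width lay between 235 and 459 bp. Read depth is not recorded in the lists, and no condition has a replicate.

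The first comparison asked how E2 changed ERα binding. E2 lengthened the peak list in 6 of 6 combinations of line and genotype, by a mean log2 ratio of 2.72 ± 1.99 (SD, n = 6 pairs), or 6.59-fold as a geometric mean (exact sign-flip permutation test, 2-sided, p = 0.03125). In MCF7 WT cells, the number of peaks within 50 kb of a TSS went from 0 to 11 at GREB1, an estrogen-induced growth regulator, from 0 to 9 at TFF1, a secreted peptide long used as a marker of estrogen response, and from 0 to 6 at XBP1, a transcription factor of the unfolded protein response. T47D WT cells went from 0 to 4 peaks at GREB1, from 0 to 1 at TFF1 and from 0 to 3 at XBP1. PGR, which encodes the progesterone receptor, had a peak in T47D WT cells with either treatment and in MCF7 WT cells with E2 only.

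The GREB1 site on chromosome 2 at 11498394 to 11499036, in an intron of the gene, held an ERE and had a score of 3100 in the MCF7 WT E2 list. At TFF1, the site on chromosome 21 at 42366135 to 42367170 was centred 118 bp from the TSS and also held an ERE. The PGR site on chromosome 11 at 101034028 to 101034508 lay in an untranslated region of the gene and held an ERE. The XBP1 site on chromosome 22 at 28813619 to 28814426 was intergenic and without an ERE. The highest score of the MCF7 WT E2 list, 3233, belonged to an ERE site on chromosome 11 at 72786237 to 72786929, in an intron of STARD10, a lipid transfer protein.

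MCF7 WT cells had 99.8 times as many peaks with E2 as with vehicle (95% interval 83.7 to 120). The ratio was 2.81 (2.57 to 3.08) in MCF7 Y537S, 5.32 (4.97 to 5.69) in MCF7 D538G, 2.80 (2.56 to 3.08) in T47D WT, 3.01 (2.81 to 3.23) in T47D Y537S and 6.51 (6.16 to 6.88) in T47D D538G. Without satellite peaks the T47D D538G lists held 9411 peaks with E2 and 994 with vehicle. Without the MCF7 WT pair the mean log2 ratio was 1.94, and with any 5 pairs the exact permutation test cannot give a p below 0.0625.

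**Figure D1:**
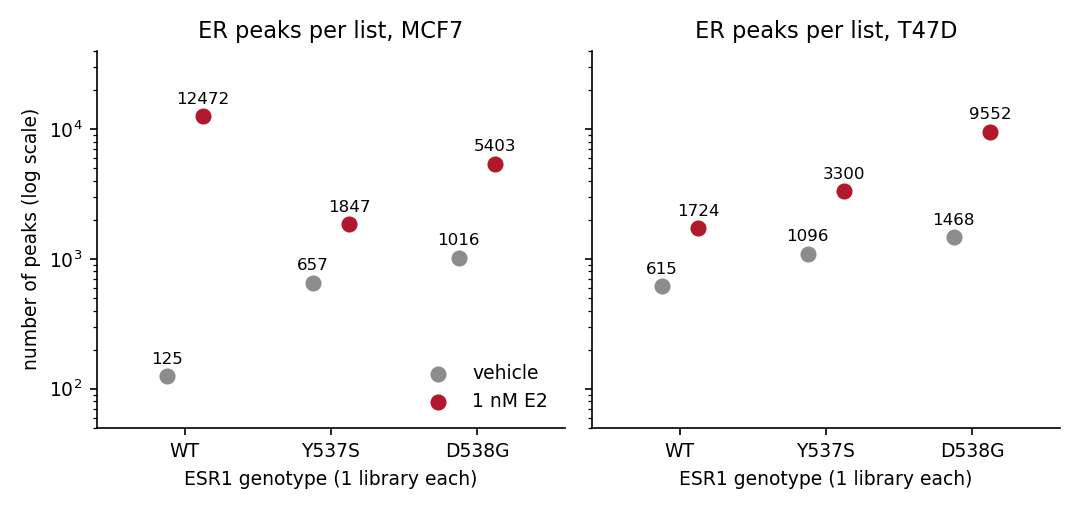
Number of ERα peaks per library (log axis) in MCF7 and T47D by ESR1 genotype, with vehicle and with E2, 1 library per point. The lists run from 125 peaks (MCF7 WT, vehicle) to 12472 (MCF7 WT, E2), and the E2 value lies above the vehicle value in all 6 pairs.

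The main question of the design was whether the mutant receptors bind chromatin without hormone. In both lines the vehicle lists of Y537S and D538G were longer than that of WT, and peaks lay near estrogen target genes that had none in the WT vehicle list. In MCF7, the WT vehicle list had no peak near any of 30 estrogen targets, the Y537S list had peaks near 6 and the D538G list near 21. GREB1 had 2 peaks in the MCF7 Y537S vehicle list, 4 in that of D538G, and 4 and 3 in the vehicle lists of T47D Y537S and D538G. At RARA, a retinoic acid receptor gene, the intronic ERE site on chromosome 17 at 40322096 to 40322842 was listed in all libraries but MCF7 WT vehicle, and so was the ERE site of EGR3, an immediate early transcription factor, on chromosome 8 at 22738942 to 22739645 in an intron of PEBP4.

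The vehicle list of MCF7 Y537S was 5.26 times as long as that of WT (4.33 to 6.42), and that of D538G 8.13 times (6.74 to 9.87). In T47D the ratios were 1.78 (1.61 to 1.97) for Y537S and 2.39 (2.17 to 2.63) for D538G. Without satellite peaks these T47D lists held 611 (WT), 1092 (Y537S) and 994 (D538G) peaks. The D538G ratio was then 1.63, and D538G no longer had the longest list. Counting only peaks with an ERE, the MCF7 ratios were at least 41.3 and at least 111, taking the floor of 3 peaks for the WT list, and the T47D ratios were 8.20 and 5.61. With E2 the lines went opposite ways, since the MCF7 mutant lists had 0.148 (Y537S, 0.141 to 0.156) and 0.433 (D538G, 0.420 to 0.447) times the peaks of WT, and those of T47D 1.91 (1.81 to 2.03) and 5.54 times (5.26 to 5.84). Each ratio sets 1 library against 1 other and was not tested alone. Within lines, the mean of the mutants' vehicle lists was above WT by a log2 difference of 1.88 ± 1.18 (SD, n = 2 lines; exact permutation p = 0.111, the smallest that 2 lines allow). Over the 4 blocks of line and treatment it was above WT in 3, by 0.87 ± 2.02 (exact permutation p = 0.284). With E2 alone the difference was -0.14 ± 2.61 (higher in 1 of 2 lines, exact permutation p = 0.778), and that of the log2 E2 to vehicle ratio was -2.02 ± 3.78 (exact permutation p = 0.333). With scores of at least 100 the MCF7 vehicle ratios were 12.7 and 16.3, and by covered base pairs 2.38 and 3.30.

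The next comparison asked whether the mutant receptor without hormone sits where the WT receptor binds with E2. Most vehicle peaks of both MCF7 mutants and of T47D Y537S lay in WT E2 peaks of the same line, among them sites at RARA, EGR3, SIAH2, an estrogen-induced ubiquitin ligase, and MYBL1, a transcription factor gene. The T47D WT vehicle list also had peaks near each of these genes. The share of vehicle peaks in WT E2 peaks was 64.4% for MCF7 Y537S (423 of 657, 60.6 to 68.0%), 68.9% for MCF7 D538G (700 of 1016, 66.0 to 71.7%), 60.2% for T47D Y537S (660 of 1096, 57.3 to 63.1%) and 33.9% for T47D D538G (498 of 1468, 31.5 to 36.4%). Each had a permutation p of 0.001, the smallest that 1000 placements can give, and random placement of the MCF7 Y537S peaks gave a mean of 0.489%. The T47D D538G list held 474 satellite peaks, and without them its share was 50.1% (498 of 994). With scores of at least 100 it was 51.3%. Among only the 500 highest scores of each list, the shares of MCF7 Y537S and D538G were 12.4% and 30.8%. The WT vehicle lists themselves had 49.6% (MCF7) and 46.2% (T47D) of their peaks in WT E2 peaks. Lying at WT E2 sites was thus not particular to the mutants, and the T47D D538G share as deposited was below that of WT. Without WT vehicle peaks the Y537S shares were 52.3% (MCF7) and 57.8% (T47D), and those of D538G 63.9% and 23.2%. Mutant and WT shares were not tested against each other.

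Seen from the WT side, vehicle peaks of the MCF7 mutants covered a small part of the WT E2 sites, 3.38% in Y537S (421 of 12472, 3.07 to 3.71%) and 5.56% in D538G (693, 5.16 to 5.97%). In T47D they covered 38.2% in Y537S (658 of 1724, 35.9 to 40.5%) and 28.3% in D538G (488, 26.2 to 30.5%). The D538G list thus covered 2.18 percentage points more of the MCF7 sites than the Y537S list (381 sites in D538G only, 109 in Y537S only, exact McNemar p = 2.3e-36), while in T47D the difference, D538G minus Y537S, was -9.86 points (51 against 221 sites, exact McNemar p = 2.14e-26). These tests compare 1 library with 1 other over sites, not the genotypes. Without satellite peaks the T47D vehicle lists held 1092 (Y537S) and 994 (D538G) peaks, and the mutant with the lower coverage had the shorter list in each line. Among the 500 highest scores of each list, with satellite peaks kept, the difference was 18.2 points in MCF7 and -8.2 in T47D. Coverage of MCF7 WT E2 sites was then 12.4% in Y537S and 30.6% in D538G. Without the peaks of the WT vehicle lists, 171 of 12173 MCF7 sites were covered in Y537S, and coverage was 18.4% in T47D D538G.

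**Figure D2:**
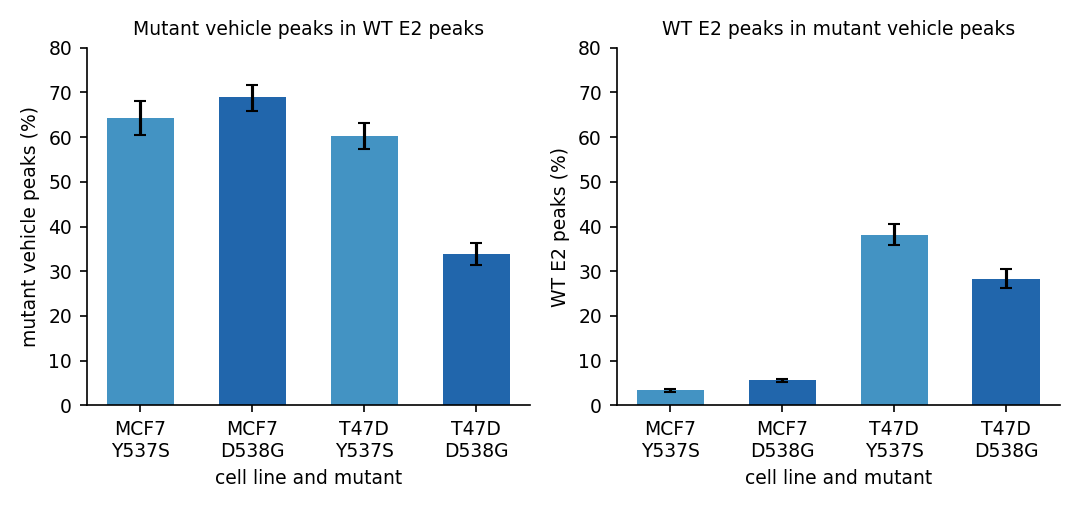
Percent of the peaks of each mutant's vehicle list that overlap the WT E2 list of the same line, and percent of WT E2 peaks that overlap the mutant's vehicle list, with 95% exact intervals for counting error. The first share lies between 33.9 and 68.9%, and the second between 3.38 and 5.56% in MCF7 and between 28.3 and 38.2% in T47D.

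Mutant-only vehicle sites, those outside every WT peak of the line, numbered 223 in MCF7 Y537S (33.9% of the list), 308 in MCF7 D538G (30.3%), 300 in T47D Y537S (27.4%) and 891 in T47D D538G (60.7%). Highest by score in MCF7 Y537S was a site on chromosome 7 at 6503582 to 6503935, in an intron of GRID2IP and nearest to the TSS of KDELR2, an endoplasmic reticulum receptor (score 262). Next came promoter sites of MDH1, a malate dehydrogenase, on chromosome 2 at 63588654 to 63589012 (257) and of WNK1, a kinase, on chromosome 12 at 752226 to 752588 (239), and promoter sites of both genes were also mutant-only in MCF7 D538G. Both regions were in 10 lists, all but the 2 of MCF7 WT, and so were called in T47D WT cells with vehicle too. In T47D Y537S, 3 of the 5 highest were blocks without an ERE on chromosome 21, outside protein-coding genes, the first at 8432009 to 8436172 (score 1621). Other blocks of several kb on chromosome 21 were among the 5 highest of T47D WT vehicle, at 8204912 to 8209202 and 8388055 to 8391651. Whether such blocks differ by genotype was not tested. The other 2 of the 5 in T47D Y537S held an ERE. They were on chromosome 18 at 22871691 to 22872111, in an intron of RBBP8, a DNA end resection factor (score 579), and on chromosome 3 at 129971386 to 129971774, intergenic near TRH, the gene of thyrotropin-releasing hormone (377). Mutant-only refers to the line, as the RBBP8 region was in 9 lists, more than the mutants have, and the TRH region in 6. In T47D D538G the highest was such a block on chromosome 21 at 8432089 to 8436169 (1998), outside protein-coding genes. All 474 satellite peaks of the T47D D538G vehicle list were mutant-only, which leaves 417.

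Mutant-only vehicle peaks held an ERE less often than vehicle peaks that also lay in a WT list. The shares were 1.35% (3 of 223) against 27.9% (121 of 434) in MCF7 Y537S (Fisher's exact test, adjusted p = 9.24e-20), 2.92% against 45.8% in MCF7 D538G (adjusted p = 1.88e-49, Fisher's exact test), 16.7% against 35.9% in T47D Y537S (adjusted p = 8.11e-10, Fisher's exact test) and 2.24% against 36.4% in T47D D538G (adjusted p = 4.93e-71, Fisher's exact test). Without satellite peaks the T47D D538G mutant-only share was 4.56% (19 of 417; adjusted p = 5.75e-36, Fisher's exact test). With scores of at least 100 the T47D Y537S shares were 35.1% and 38.5% (adjusted p = 0.564, Fisher's exact test). The 2 mutants shared 40 mutant-only vehicle sites in MCF7 (17.9% of those of Y537S) and 32 in T47D (10.7%), with 0 and 7 EREs. Across lines, 21 Y537S-only and 16 D538G-only sites were shared. Each of these 4 overlaps had a permutation p of 0.001, the smallest that can be had. Merging vehicle and E2 lists gave 384 mutant-only sites in MCF7 Y537S (18.3%), 950 in MCF7 D538G (16.7%), 1889 in T47D Y537S (53.9%) and 8361 in T47D D538G (82.0%), beside WT E2 lists of very different length.

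A further comparison asked which sites the lines have in common. With E2, 82.4% of the T47D WT peaks (1421 of 1724) lay in MCF7 WT peaks, among them those at GREB1, XBP1 and CTSD, which encodes the protease cathepsin D. The share of the shorter list was 56.1% for Y537S with E2, 62.4% for D538G with E2, 59.8% (393 of 657) for Y537S with vehicle, 36.8% (374 of 1016) for D538G with vehicle and 58.4% (73 of 125) for WT with vehicle, each with a permutation p of 0.001, the smallest possible. For the 500 highest scores of the WT E2 lists the share was 37.0%, for WT vehicle peaks with scores of at least 100 it was 95.7%, and without the WT vehicle peaks it was 31.4% for Y537S and 22.9% for D538G with vehicle. Within T47D, 84.5% of the WT E2 peaks lay in the Y537S E2 list and 96.2% in the D538G E2 list. Within MCF7, 87.3% of the Y537S E2 peaks and 86.8% of the D538G E2 peaks lay in the WT E2 list.

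Sequence under the peaks was then compared. The palindromic ERE, to which the receptor binds as a dimer, was more frequent than at random in 11 of the 12 lists (permutation p = 0.0099 each, the smallest that 100 placements can give). In the MCF7 vehicle lists it was found in 0 of 125 WT peaks, which allows a share of up to 2.4%, in 18.9% of Y537S peaks (16.0 to 22.1%) and in 32.8% of D538G peaks (29.9 to 35.8%). T47D vehicle lists had it in 6.67% of WT peaks (4.83 to 8.94%), 30.7% of Y537S peaks and 15.7% of D538G peaks. The E2 lists had 24.8% (WT), 34.8% (Y537S) and 1623 of 5403 peaks (D538G) in MCF7, and 35.5%, 30.8% and 25.1% in T47D. Random placement gave 1.02% for MCF7 WT E2 and 0.774% for T47D WT vehicle. Without satellite peaks 229 of 994 peaks of T47D D538G vehicle held an ERE, and with scores of at least 100 the share was 27.1%. A perfect ERE was found in 4.71% of MCF7 WT E2 peaks, 10.5% of MCF7 D538G vehicle peaks and 11.4% of T47D Y537S vehicle peaks.

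Of the other motifs, the forkhead motif, which FOXA1 binds, and the AP-1 motif were more frequent than at random in all 6 E2 lists, by 1.5 to 1.88 times and 1.59 to 2.08 times (permutation p = 0.0099 each, the smallest possible). The single arm of the ERE (GGTCA) was more frequent in all lists but the WT vehicle ones, and the AP-2 motif in all 12, by 1.87 to 3.81 times, each with the same permutation p. The CTCF motif, taken as a control, was also more frequent than at random in 11 lists, all but MCF7 WT vehicle (1.38 to 2.44 times, permutation p of 0.0099 to 0.03), so that an excess over random placement was not particular to the forkhead and AP-1 motifs. GATA motifs were 1.20 times as frequent as at random in MCF7 Y537S E2 peaks, and less frequent in all 6 T47D lists (0.359 to 0.822 times) and the 3 MCF7 vehicle lists (0.519 to 0.724 times), each with a permutation p of 0.0099. For MCF7 WT and D538G with E2 the GATA ratios, 0.990 and 0.995, turned to 1.12 and 1.12 when random regions lay within 10 to 100 kb of the peaks (permutation p = 0.0099 each). Random placement kept chromosome and width but not base composition or distance to a TSS. The AP-2 excess and the lower GATA shares were therefore not shown to be particular to ERα sites.

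**Figure D3:**
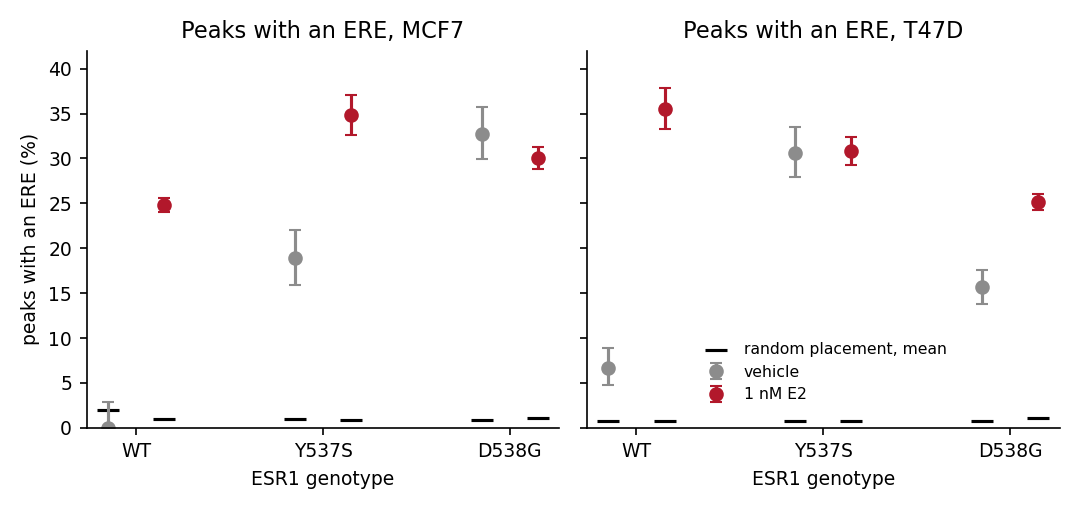
Percent of the peaks of each list with a palindromic ERE (at most 1 mismatch), with 95% exact intervals for counting error, and dashes for the mean of random placements. The share is 0 in MCF7 WT vehicle and 6.67% in T47D WT vehicle, and between 15.7 and 35.5% in the other 10 lists.

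Peaks of all 12 lists lay at promoters more often than at random, by 2.33 times in MCF7 WT E2 to 10.1 times in T47D WT vehicle (permutation p = 0.0099 each, the smallest possible). The share within 1 kb of a TSS was 42.7% (50 of 117 peaks on chromosomes 1 to 22 and X, 33.6 to 52.2%) in MCF7 WT vehicle and 11.2% in MCF7 WT E2, and 54.8% and 17.0% in T47D WT. In Y537S it was 47.4% with vehicle and 13.8% with E2 in MCF7, and 33.5% and 17.5% in T47D. In D538G it was 25.3% and 12.5% in MCF7, and 19.0% and 14.6% in T47D. Within 3 kb, the E2 shares were 20.1% (WT), 21.3% (Y537S) and 20.5% (D538G) in MCF7 and 22.6% in T47D D538G. E2 peaks that were also in the vehicle list of the same cells were at promoters more often than E2-only peaks in all 6 pairs. The difference was smallest in T47D D538G (30.3% against 13.1%, Fisher's exact test, adjusted p = 8.16e-30) and MCF7 D538G (27.4% against 10.0%, Fisher's exact test, adjusted p = 6.05e-33). It was largest in MCF7 WT (72.1% against 10.9%, Fisher's exact test, adjusted p = 8.26e-29). The E2 peaks shared with vehicle held an ERE less often than E2-only peaks in MCF7 WT (0 of 61 against 24.9%, Fisher's exact test, adjusted p = 1.33e-07), MCF7 Y537S (30.1% against 36.1%, 0.0413) and T47D WT (15.0% against 39.3%, 8.41e-15). They held one more often in MCF7 D538G (44.2% against 27.8%, adjusted p = 1.9e-17, Fisher's exact test), T47D Y537S (38.6% against 28.0%, 3.27e-08) and T47D D538G (32% against 24.6%, 5e-05). In 200 bp around the centre the T47D D538G shares were 25.4% and 22.4% (adjusted p = 0.103, Fisher's exact test), the median widths being 639 and 450 bp, and without satellite peaks they were 37.9% and 24.7% over the whole peak (adjusted p = 6.19e-12). With a perfect ERE the differences in MCF7 WT and T47D WT did not pass (adjusted p = 0.132 each, Fisher's exact test), nor did that in MCF7 Y537S, where the shares were 9.80% in both classes (adjusted p = 1, and 0.429 with scores of at least 100).

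The 5 regions present in all 12 lists with the highest mean rank held no ERE. The first lay on chromosome 17 at 82592561 to 82593673, in an intron of FOXK2, a forkhead transcription factor, 283 bp from a TSS. The others were on the contig 17_GL000205v2_random, in intergenic sequence of chromosome 21 at 8986543 to 8989092 and at 6369194 to 6372571, and at the promoter of UCKL1, a uridine kinase-like gene, on chromosome 20 at 63956221 to 63956835. In all, 41 of 18779 merged regions were in 12 lists, 0 of them with an ERE, and 10839 were in 1 list.

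Genes near the peaks were compared by lists. Of 30 estrogen targets, 28 had a peak within 50 kb in at least 1 library, and CXCL12 and OLFM1 had none. The list stood above random gene lists in 10 of 12 libraries, and in 11 when adjusted over the list alone. With E2, 28 of 30 targets had a peak in MCF7 WT (13.2 at random), 22 in MCF7 Y537S (3.06), 25 in MCF7 D538G (7.60), 19 in T47D WT (3.03), 26 in T47D Y537S (5.59) and 28 in T47D D538G (11.7). With vehicle, 0 had one in MCF7 WT, 6 in MCF7 Y537S (1.90), 21 in MCF7 D538G (2.28), 7 in T47D WT (1.99), 18 in T47D Y537S (2.68) and 16 in T47D D538G (2.12). The permutation p was 0.0001 (adjusted 0.0013), the smallest that 10000 lists can give, in all of these but MCF7 WT vehicle, MCF7 Y537S vehicle (adjusted permutation p = 0.092, and 0.012 when adjusted over the list alone) and T47D WT vehicle (adjusted permutation p = 0.025). With a 20 kb window the counts in MCF7 Y537S, T47D Y537S and T47D WT vehicle were 3, 10 and 3, the last with an adjusted permutation p of 0.63. Without WT vehicle peaks the counts in MCF7 Y537S and T47D D538G vehicle were 2 and 10.

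Sites of the same position recurred across the mutant vehicle lists. IGFBP4, an insulin-like growth factor binding protein, had an intronic ERE site on chromosome 17 at 40448316 to 40449186, and KRT13, a keratin, an intergenic ERE site on the same chromosome at 41535809 to 41536544, both listed in 9 libraries including the vehicle lists of MCF7 D538G and both T47D mutants. An intronic ERE site of SIAH2 on chromosome 3 at 150756496 to 150756813 was in 11 libraries. The site near CTSD on chromosome 11 at 1796250 to 1797060, without an ERE, was in 9. Other targets had peaks in few libraries: CCND1, which encodes cyclin D1, and MYC only in MCF7 WT and T47D D538G with E2 (for each, a region beyond 50 kb was in 10 lists), and RET, a receptor tyrosine kinase gene, in 4 E2 lists. In T47D, 8 targets had a peak in a mutant list and none in a WT list, while in MCF7 3 had a WT peak and no mutant peak, beside WT E2 lists of 1724 and 12472 peaks.

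**Figure D4:**
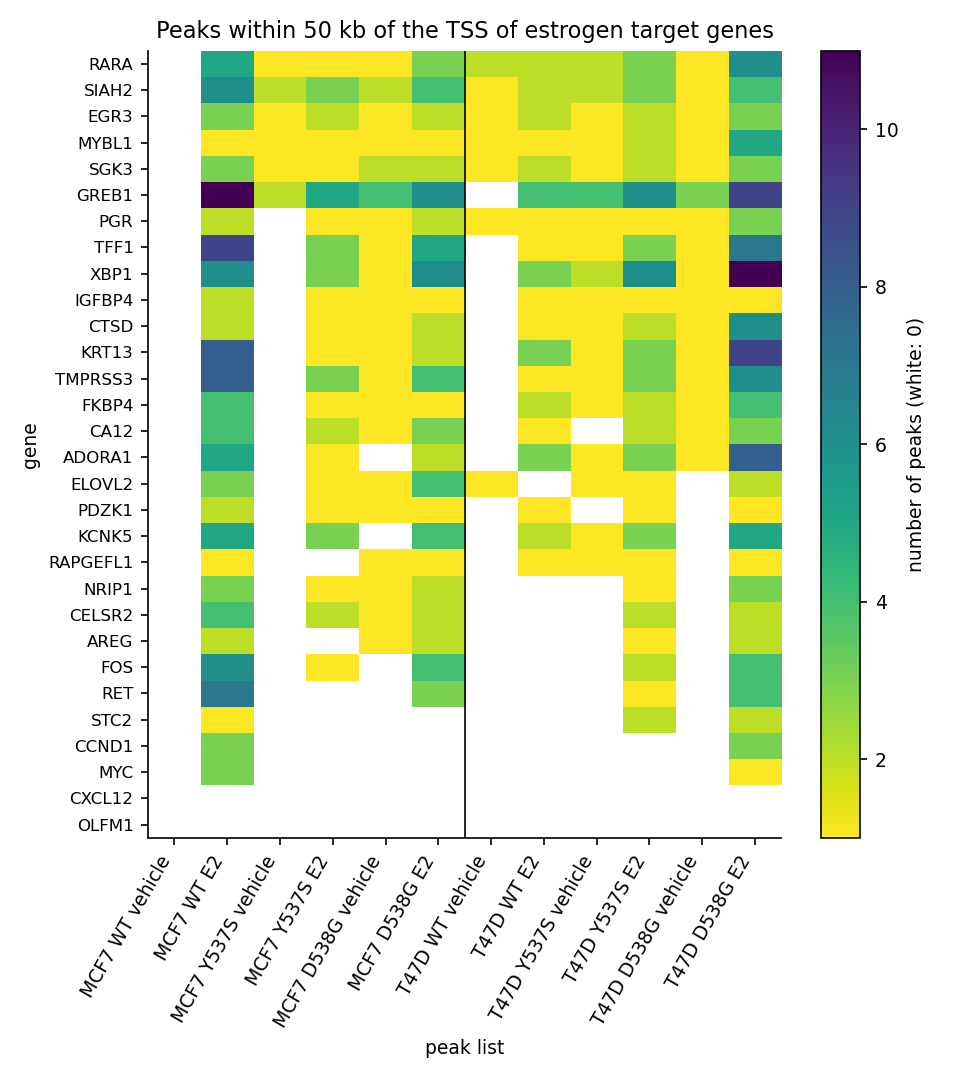
Number of ERα peaks within 50 kb of a TSS for each of 30 estrogen target genes (vertical) in the 12 peak lists (horizontal). GREB1 has 0 peaks in MCF7 WT vehicle, 11 in MCF7 WT E2, 2 in MCF7 Y537S vehicle and 4 in MCF7 D538G vehicle, and CXCL12 and OLFM1 have 0 in all lists.

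Luminal regulators, the transcription factors and cofactors of the luminal breast lineage, stood above random lists in 4 libraries, and in 5 when adjusted over the list alone. Of 18 members, 16 had a peak in MCF7 WT E2 (adjusted permutation p = 0.0022), 12 in MCF7 D538G E2 (adjusted permutation p = 0.0061), 11 in T47D Y537S E2 (adjusted permutation p = 0.0022) and 16 in T47D D538G E2 (adjusted permutation p = 0.0013). Within 100 kb the call in MCF7 WT E2 was lost (16 members, adjusted permutation p = 0.074) and one was gained in MCF7 D538G vehicle (8 members, adjusted permutation p = 0.011). FOXA1, a pioneer factor for ERα, had no peak in the T47D WT lists but had one in 3 T47D mutant lists, the highest on chromosome 14 at 37546616 to 37547326, in an untranslated region of MIPOL1. In MCF7 the reverse held, with 4 FOXA1 peaks in WT E2 and 0 in every mutant list. The WT E2 lists held 1724 (T47D) and 12472 (MCF7) peaks. GATA3, a luminal transcription factor, had a peak on chromosome 10 at 8084701 to 8085523, intergenic, in the E2 lists of both T47D mutants, MCF7 WT and MCF7 D538G.

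The other 9 lists were called in 0 libraries, also when adjusted over the list alone, but within 100 kb basal markers were called in 5. Random gene lists make no allowance for members that lie close together and share a peak. Among basal markers, KRT14 and KRT15 had peaks within 50 kb in the same 9 libraries. The lowest adjusted permutation p was 0.15 for basal markers, 1 for cell cycle, 1 for epithelial-mesenchymal transition and migration, 0.4 for housekeeping, 0.29 for insulin-like growth factor and insulin, 0.28 for junctions and adhesion, 0.63 for matrix proteases, 0.73 for other tissues and 0.24 for the Wnt pathway. Single members still had recurrent sites. An ERE site in an intron of IGF1R, the insulin-like growth factor receptor, on chromosome 15 at 98749070 to 98749752, was listed in 10 libraries, all but the WT vehicle ones. AXIN1, a scaffold protein of Wnt signalling, had an intronic ERE site on chromosome 16 at 316741 to 317370 in 6 libraries. CDH1, which encodes E-cadherin, had a site on chromosome 16 at 68745626 to 68746092 in the 3 MCF7 E2 lists and T47D D538G E2. JUP, which encodes the junction protein plakoglobin, had one on chromosome 17 at 41793013 to 41793624 in 4 E2 lists. ITGB4 and RPL13A had peaks within 50 kb in all 12 libraries, the WT vehicle ones included, and RPL13A is a ribosomal protein gene of the housekeeping list. Peaks within 50 kb can lie at a neighbouring gene.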

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

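The tests of a single ranking of sites, of the number of peaks in the MCF7 WT vehicle list and of its overlap with T47D were chosen after the results were seen, and the other tests were set beforehand.

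With E2 the mutant lists were shorter than WT in MCF7 (0.148 and 0.433 times for Y537S and D538G) and longer in T47D (1.91 and 5.54 times), and this difference between the lines was not tested. An effect of the mutations that differs between the lines remains open and untested. Depth may order the lists, but over the 6 E2 lists the median score at regions called in all 12 lists gave a Spearman rho of 0.6 with list length (exact permutation p = 0.242) and a Pearson r of 0.438 (exact permutation p = 0.396; 0.540 without MCF7 WT and T47D D538G), so depth and genotype cannot be told apart with 1 library each and scores that need not be comparable between lists. One ranking of sites read to different depths is a candidate explanation, since at least 86.8% of the peaks of each shorter E2 list lay in the longest E2 list of its line. Peaks of the longest list that were shared with the shortest had higher scores than the rest (median 691 against 107 in MCF7 and 925 against 104 in T47D). Nesting of this kind cannot tell depth from a difference in binding strength at the same sites, so it does not favour depth over genotype.

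D538G covered more of the WT E2 sites than Y537S in MCF7 (2.18 percentage points) and fewer in T47D (-9.86 points), in lists of 1 library each, where the lower coverage went with the shorter list once satellite peaks were left out (657 against 1016 peaks deposited in MCF7, 994 against 1092 without satellite peaks in T47D), and the difference between the lines was not tested. Among the 500 highest scores of each list, where these lists are equally long, both directions held (18.2 points in MCF7 and -8.2 in T47D). Satellite peaks were not left out there and may be among the 500 of T47D D538G. The T47D value is therefore not a comparison at equal length without satellite peaks.

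The MCF7 WT vehicle list held no ERE. Counting error alone does not account for this, since 0 of 125 allows at most 2.4% and the lowest share among the mutant vehicle lists was 15.7%. That limit treats the peaks as a random draw. A library of low depth need not list peaks at random, so low depth is not excluded. The list may consist in good part of regions that are called in libraries of either line, as 58.4% of its peaks (73 of 125) overlapped a T47D WT vehicle peak. That overlap compares vehicle with vehicle. Of its peaks, 49.6% overlapped an MCF7 WT E2 peak, so not all of its regions were called whatever the treatment. That it is a set of open promoters remains open, with 42.7% of the peaks within 1 kb of a TSS against 5.42% at random. The inputs were not analysed here, and no biological explanation was tested.

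In T47D D538G vehicle, 265 peaks (18.1%) lay on contigs outside chromosomes 1 to 22 and X. EREs on these contigs do not account for them, since 0.755% of the peaks (2 of 265) held one. Satellite repeats are a candidate source, as 77.7% (206 of 265) had at least 10% of their bases in the GGAAT word. Over the whole list 474 of 1468 peaks (32.3%) were satellite peaks, and T47D D538G with E2 held 141 (1.48% of 9552), against at most 16 in each of the other 10 lists. The list with 16 was MCF7 D538G vehicle. By share, that list (1.57%) and MCF7 WT vehicle (1.6%, 2 of 125) were slightly above T47D D538G with E2. Whether genotype, the clones or the input control set the T47D D538G libraries apart in these counts was not tested.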

How the results depend on the processing

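The tests of mutant against WT list lengths in blocks or pairs and alternatives that count ERE peaks only, leave out WT vehicle peaks or leave out satellite peaks were chosen after the data were seen, and the others were planned. Of 793 alternative values, 708 kept their direction and their side of the threshold or stayed near the value reported, 19 no longer passed the threshold, 5 newly passed it, 47 moved and 14 changed direction. The cause was not tested except where stated. The lists limit all results by unknown depth, and 1 library decides each value.

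Leaving out each pair of lists in turn, the mean log2 ratio of E2 to vehicle peak numbers ranged from 1.94 to 2.97 and lost its call (exact permutation p = 0.0625, the smallest that 5 pairs allow).

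Paired by line and treatment, the log2 ratio to WT averaged 0.35 for Y537S (exact permutation p = 0.75) and 1.39 for D538G (exact permutation p = 0.25), where 4 pairs allow no p below 0.125. Mutant to WT ratios of peak numbers kept their direction. With scores of at least 100 they were 12.7 (Y537S) and 16.3 (D538G) in MCF7 vehicle, 0.131 and 0.399 in MCF7 E2, 1.65 for T47D D538G vehicle, and 2.03 and 6.02 in T47D E2. By base pairs covered they were 2.38 and 3.30 in MCF7 vehicle, 0.132 and 0.448 in MCF7 E2, 1.56 for T47D Y537S vehicle and 7.66 for T47D D538G E2. Counting ERE peaks only gave at least 41.3 and at least 111 in MCF7 vehicle, 0.208 and 0.524 in MCF7 E2, 8.20 and 5.61 in T47D vehicle, and 1.66 and 3.92 in T47D E2. T47D D538G vehicle gave 2.04 on chromosomes 1 to 22 and X and 1.63 without satellite peaks. In blocks, counting ERE peaks only, with the floor of 3 peaks for MCF7 WT vehicle, moved the log2 differences. They were 4.42 with vehicle (exact permutation p = 0.111), -0.12 with E2 (0.778) and 2.15 over the 4 blocks (0.0864). That of the log2 E2 to vehicle ratio was -4.55, higher in the mutants in 0 of 2 lines (exact permutation p = 0.111, the smallest possible).

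Mutant-only vehicle sites (MCF7 Y537S, MCF7 D538G, T47D Y537S, T47D D538G) numbered 104, 50, 94 and 188 with scores of at least 100, and 3, 10, 50 and 20 with an ERE when the WT lists also held ERE peaks only. The 500 highest scores gave 371 for MCF7 Y537S and 93 and 184 for T47D Y537S and D538G, and 417 were left in T47D D538G without satellite peaks. For vehicle and E2 merged, the numbers were 144, 178, 1006 and 4773 with scores of at least 100, and 18, 85, 462 and 1800 with an ERE. The 500 highest scores gave 344 for MCF7 D538G and 172 and 318 for T47D Y537S and D538G.

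Directions against random placement changed for cofactor motifs near a ratio of 1. In 200 bp around the centre the ratio was 0.641 for CTCF in MCF7 WT vehicle, 1.10 for GATA in MCF7 WT E2, 1.12 for GATA in MCF7 D538G E2 and 1.11 for forkhead in T47D WT vehicle. With moves of 10 to 100 kb it was 1.12 and 1.12 for the GATA ratios, 1.06 for the forkhead ratio and 1.15 for AP-1 in T47D D538G vehicle. Under both alternatives each of these GATA ratios had a permutation p of 0.0099, the smallest possible. The CTCF motif in MCF7 Y537S E2 no longer passed in 200 bp around the centre (ratio 1.36, permutation p = 0.079). Luminal regulators in T47D WT vehicle, near the random expectation, numbered 1 within 20 kb and 3 within 100 kb. Elsewhere this list lost its call in MCF7 WT E2 within 100 kb (adjusted permutation p = 0.074) and gained one in MCF7 D538G vehicle within 100 kb (0.011), MCF7 Y537S E2 within 20 kb (0.047) and T47D WT E2 without WT vehicle peaks (0.031).

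Between classes of peaks, differences are in percentage points with adjusted p from Fisher's exact tests. The ERE difference of E2 peaks shared with vehicle minus E2-only peaks fell to 3.07 in T47D D538G in 200 bp around the centre (Fisher's exact test, p = 0.103). With a perfect ERE it was -4.73 in MCF7 WT (p = 0.132), -3.28 in T47D WT (p = 0.132) and 0.00545 in MCF7 Y537S (p = 1, Fisher's exact tests), and with scores of at least 100 it was -3.86 in MCF7 Y537S (p = 0.429). Vehicle peaks in a WT list minus mutant-only peaks gave an ERE difference of 3.37 in T47D Y537S with scores of at least 100 (Fisher's exact test, p = 0.564). The promoter difference between these classes was 1.03 in MCF7 Y537S (p = 0.805), 8.75 in MCF7 D538G (p = 0.00367), 36.3% against 23.3% in T47D Y537S (p = 4.7e-05) and 31.8 in T47D D538G (p = 8.49e-62, Fisher's exact tests). With scores of at least 100 the first 3 turned to -20.9 (p = 0.000665), -45.5 (p = 9.42e-10) and -4.11 (p = 0.475, Fisher's exact tests).

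Estrogen targets in T47D WT vehicle lost their call within 20 kb (3 genes, adjusted permutation p = 0.63) and with scores of at least 100 (4 genes, adjusted permutation p = 0.19). In MCF7 Y537S vehicle they gained one with scores of at least 100 (5 genes, adjusted permutation p = 0.037). The 9 gene lists called in no library in the reported setting are represented by the number of libraries called. That number became 5 for basal markers within 100 kb, where neighbouring members can share a peak. Without WT vehicle peaks the MCF7 and T47D overlap of the WT vehicle lists has no value, as no peaks remain.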

Other observations

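All tests in this part were chosen after the data were seen.

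A small set of regions was bound in every mutant vehicle list and in neither WT vehicle list. There were 50 such regions, 36 of them with an ERE (72%) and 4 at a promoter (8%), against 6.85% with an ERE and 52.0% at promoters among 613 regions of the WT vehicle lists. Before regions of the WT vehicle lists were left out, 214 regions were in all 4 mutant vehicle lists, 28.5% with an ERE and 56.1% at promoters. Regions in all 6 E2 lists and no WT vehicle list had shares of 54.2% and 6.98%, so the low promoter share was not particular to the 50 regions. Of the 50, 44 were also in both WT E2 lists, and 2 were in no WT list. By mean rank the first were in introns of AFF3 on chromosome 2 at 99636409 to 99637233, of FSIP1 on chromosome 15 at 39668239 to 39669060, of EPS15L1 on chromosome 19 at 16463536 to 16464473 and of GREB1 on chromosome 2 at 11498394 to 11499036, the last 3 with an ERE. AFF3 encodes a nuclear transcription elongation factor. Intergenic members included a region on chromosome 10 at 44172785 to 44174080, 211610 bp from the nearest TSS, that of the chemokine gene CXCL12, and one on chromosome 8 at 127869782 to 127871220, 131428 bp from the TSS of MYC, and an ERE region on chromosome 11 at 69515112 to 69516000, 125600 bp from the TSS of CCND1, all beyond the 50 kb window used for genes. These genes were named after their values were seen.

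Sites of 1 line only differed in their GATA content. Of the regions in all 3 MCF7 E2 lists and no T47D list (265), 80.8% held a GATA motif, against 54.3% of the regions in all 3 T47D E2 lists and no MCF7 list (129; Fisher's exact test, adjusted p = 6.37e-07). In 200 bp around the centre the shares were 52.1% and 24.0% (Fisher's exact test, adjusted p = 6.44e-07), and median widths were 563 and 566 bp. Single ERE arms (GGTCA) were also more frequent in the MCF7 set (91.3% against 79.8%, Fisher's exact test, adjusted p = 0.00642), while the palindromic ERE (31.3% against 25.6%, adjusted p = 0.467, Fisher's exact test) and the forkhead motif (11.3% against 17.1%, adjusted p = 0.356, Fisher's exact test) did not pass. The leading MCF7 sites were on chromosome 1 at 111513218 to 111514029, in an intron of TMIGD3 near the adenosine receptor gene ADORA3, and at 164748166 to 164749104, in an intron of PBX1, a homeodomain transcription factor. In T47D they were on chromosome 17 at 57948072 to 57948786, in an intron of CUEDC1 and with an ERE, and on chromosome 14 at 94330642 to 94331470, near SERPINA6, which encodes corticosteroid-binding globulin. Peak lists of 1 library per condition cannot show whether such sites differ between the lines or between these libraries.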
